A study of Homo sapiens with 12 samples.

How the data were processed

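RNA from BxPC-3 cells, an established epithelial line from a human pancreatic tumour, was sequenced in 12 libraries in 4 groups of 3: DMSO, ZG111 at 20 µM, sterile water, and doxycycline (Dox) at 1 µg/mL. Per the labels' protocols, RNA was extracted with TRIzol, messenger RNA was selected on oligo(dT) beads, and paired-end libraries were read on a NovaSeq instrument. The deposited values are TPM per gene (transcript abundance scaled by length and to a fixed library total), 61033 genes per library, which the authors made before deposit. Per the submitters' processing notes, HISAT2 2.1.0, RSEM 1.3.1 and DESeq2 1.24.0 were used, with no role given for each. The genome build and the use of strand in counting are not given in the sources used here. TPM divides each library by its own total, so all libraries have the same sum and a large gain in a few genes lowers the values of all others. TPM keeps no read depth: the depth per library is unknown, and no counting interval is given.

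Groups and replicate numbers came from the labels. Nothing in the labels says whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Genes with at least 1 TPM in at least 3 of the 12 libraries were kept, which left 16212 genes, among them 311 without a symbol. Values were tested as log2(TPM + 1) in a fit of all 4 groups with limma 3.58.1 in R 4.3.3, with a variance trend over mean expression and no covariates. Adjusted p-values are by the Benjamini-Hochberg method over all genes tested, two-sided, and a gene was called at adjusted p under 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. The contrasts were ZG111 minus DMSO, Dox minus water, the second minus the first, and water minus DMSO. A fit to a simulated change of 200 among the 16212 genes recovered 59.7%, 89.6% and 100% of genes changed 1.5-fold, 2-fold and 4-fold in the ZG111 comparison with 6 false calls. In the Dox comparison it recovered 56.7%, 92.5% and 100%, with 5 false calls. The changed genes were drawn only from those above 5 TPM in DMSO, so recovery of lower genes was not simulated. Noise was normal, independent between genes and equally wide in all groups. As many genes were raised as lowered, and values were not rescaled to a fixed sum. False calls from a shift of most genes or from unequal spread between groups were therefore not simulated. Both runs used the DMSO means and the same variances, so the second is no separate test of the Dox libraries.

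Before the data were examined, 31 gene lists were fixed, with 682 entries, of which 647 passed the filter. Lists were compared with all other genes by camera in limma with a preset correlation between genes of 0.01, two-sided, adjusted over 30 lists. The list of acinar, endocrine and hepatocyte markers had 1 tested member and was not tested. The test was repeated with a correlation estimated from the residuals. Called members were also counted with p-values adjusted over the list alone. The share of TPM in the 13 mitochondrially encoded mRNAs was compared by exact two-sided permutation tests, for which 3 against 3 libraries give no p below 0.1.

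The rule for named genes was also fixed then: CLPP and CLPX; the 6 largest called rises and falls per comparison with a symbol, at least 5 TPM in the higher group and no overlap between groups; up to 3 called members per list in the direction of its test; 4 genes per direction called in both comparisons; 5 per direction for the difference; and 3 per direction for water against DMSO. Genes without a symbol, ribosomal RNA and pseudogenes were skipped, by the gene types of GENCODE 29, which held 15754 of the tested genes. A gene that the rule takes is not reported here. Other genes named in the text were chosen after their values were seen. Coordinates are those of GENCODE 29 on GRCh38, matched by Ensembl identifier.

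The alternatives were other pseudocounts (0.1 and 5), no filter or a mean of at least 5 TPM, median-ratio scaling, quantile normalization, rescaling without mitochondrial genes, only the 6 libraries of a comparison, a replicate block, no variance trend, library weights, stricter thresholds, an estimated correlation, and leaving out each of the 12 libraries. Figures were drawn with matplotlib 3.10.9.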

Results

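Gene expression was measured by RNA sequencing in 12 libraries of BxPC-3 cells, 3 in each of 4 groups. ZG111 is a compound known here by its code, which the series text sets beside activation of ClpP, the proteolytic subunit of a protease of the mitochondrial matrix. Dox is doxycycline, a common inducer of introduced genes, and the series text also names a mutant ClpP; the labels do not describe the introduced gene. Between 21726 and 25484 genes were above 0 per library, and read depth was unknown. Correlations of log2 values within a group ran from 0.972 to 0.984 across genes. The first principal component held 45.1% of the variance and set the 3 ZG111 libraries apart from the other 9.

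CLPP itself checked the Dox label. CLPP (ENSG00000125656, chromosome 19, 6361452 to 6368910) stood at 41.1 ± 2.31 TPM in water and 846 ± 25.5 TPM in Dox (SD, n = 3 each), a ratio of 20.6. Its log2 fold change was 4.33 (SE 0.09, limma adjusted p = 2.49e-10), and the exact two-sided permutation p was 0.1, the smallest possible. In DMSO and ZG111, CLPP stood at 34.5 ± 4.23 and 35.7 ± 3.53 TPM (log2 fold change 0.05, limma adjusted p = 0.681). Over 23 alternative settings this fold change ran from -0.07 to 0.31, so its sign and size depended on the processing. CLPX (ENSG00000166855, chromosome 15, 65148219 to 65185342), which encodes the unfoldase partner of ClpP, was at 47.1 ± 1.06 TPM in DMSO, 40.3 ± 1.75 in ZG111, 47.7 ± 2.31 in water and 55.2 ± 1.92 in Dox. It was called lower with ZG111 (log2 fold change -0.22, adjusted p = 0.0109), but under median-ratio scaling the value was 0.04 (adjusted p = 0.657).

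**Figure D1:**
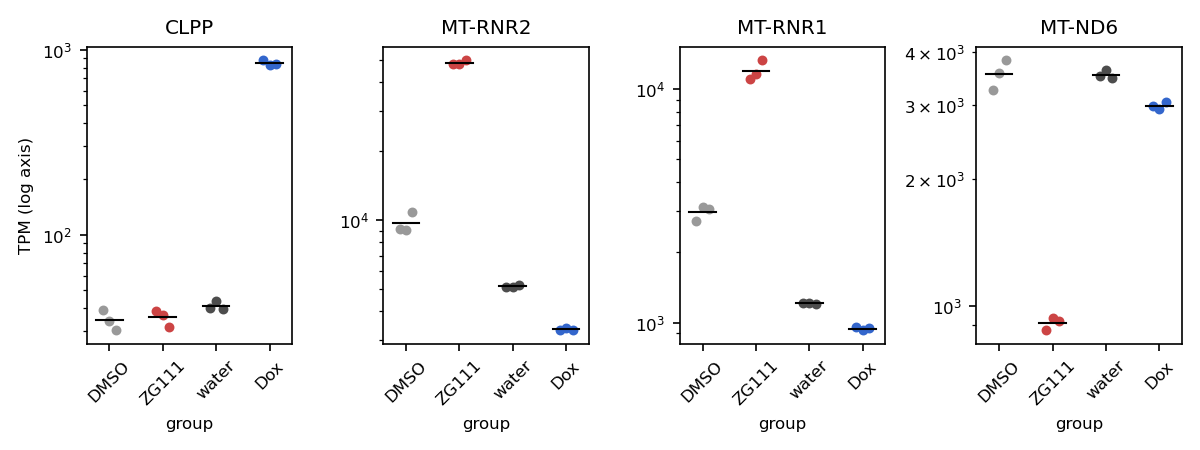
TPM on a log axis of CLPP, MT-RNR2, MT-RNR1 and MT-ND6 in each library (points) with group means (lines), 3 libraries per group. CLPP was near 846 TPM in Dox and below 44 TPM in every other library.

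The first comparison asked what ZG111 changed against DMSO. All 39 tested genes of DNA replication and all 35 of mitosis were called lower, and 26 of 29 interferon response genes were called higher. UHRF1, a factor in copying DNA methylation, fell from 16.1 ± 4.07 to 1.25 ± 0.136 TPM (SD, n = 3). GDF15, a secreted stress cytokine, rose from 208 ± 38.8 to 1207 ± 435 TPM, and GPNMB, a membrane glycoprotein, from 3.82 ± 0.145 to 31.4 ± 7.13 TPM. The secreted proteins SPP1 (log2 fold change 2.56) and FGF19 (2.13) were also among the 6 largest rises. In all, 2114 genes were called higher and 5799 lower, of which 254 and 1234 changed at least 2-fold.

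All 39 tested genes of DNA replication fell (median log2 fold change -1.67, camera adjusted p = 3.42e-16; adjusted p = 0.199 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, changed by -2.54 (SE 0.35, adjusted p = 0.000147), and PCNA, the sliding clamp, went from 218 ± 53.1 to 65.5 ± 5.72 TPM. All 35 genes of mitosis fell (median -1.39, adjusted p = 9.87e-10; adjusted p = 0.363 with an estimated correlation), among them NDC80 (-2.11), the proliferation marker MKI67 (-2.02) and the kinase AURKB (-1.94). Other large falls were FAM111B (-3.02), PCLAF (-2.82), CDCA7 (-2.64) and AC087632.2 (-3.02), which overlaps PCLAF on the same strand, so their reads are hard to separate. CDKN1A, an inhibitor of cyclin-dependent kinases, rose by 0.62 (adjusted p = 0.00147), while the list of p53 targets was not called (9 higher and 7 lower of 23, adjusted p = 0.0577).

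Of 29 interferon response genes, 26 rose and 1 fell (median 0.88, camera adjusted p = 1.05e-17, and adjusted p = 0.0799 with an estimated correlation). Water minus DMSO, a difference without either treatment, gave this list a median of nearly the same size (0.84). IFI44L rose from 4.84 ± 1.28 to 28.5 ± 6.96 TPM, MX1, an antiviral GTPase, from 8.19 ± 0.599 to 39.2 ± 9 TPM, and IFIT1 from 2.7 ± 0.417 to 13.5 ± 3.95 TPM. NRF2 targets rose in 14 of 22 with no fall (median 0.40, adjusted p = 1.23e-07; 0.13 as the adjusted p with an estimated correlation), led by the ferritin light chain FTL (3215 ± 182 to 7698 ± 1842 TPM), TKT (1.20) and OSGIN1 (0.98). Among immediate early genes, 11 of 22 rose and 2 fell (adjusted p = 3.2e-05; adjusted p = 0.275 with an estimated correlation). The leading members were the phosphatases DUSP5 (1.89) and DUSP1 (1.53) and the factor ATF3 (1.59), and JUN rose by 0.65 (adjusted p = 0.00207). NF-kB targets rose in 9 of 19 and fell in 3 (adjusted p = 0.000805; adjusted p = 0.13 with an estimated correlation), among them IL1B (1.85), RELB (1.08) and IL1A (0.96). Fatty acid synthesis (4 higher, 2 lower of 12, adjusted p = 0.0134; 0.363 as the adjusted p with an estimated correlation) was led by SREBF1 (0.84), FASN (0.76) and SCD (0.64). The list of the BCL2 family and death receptors had 5 higher and 2 lower of 18 (adjusted p = 0.0139, and adjusted p = 0.13 with an estimated correlation). It was led by BBC3 (0.94), the death receptor TNFRSF10B (0.56) and PMAIP1 (0.49).

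Of 15 integrated stress response factors, 8 rose and 5 fell (adjusted p = 0.0189; adjusted p = 0.445 with an estimated correlation), with GDF15 (2.49), ATF3 (1.59) and DDIT3 (1.27) higher and CHAC1 lower (-1.76). Of 15 genes of serine, one-carbon, proline and asparagine synthesis, 13 fell and none rose (median -0.86, adjusted p = 0.000205; adjusted p = 0.275 with an estimated correlation). PSAT1, an enzyme of serine synthesis, fell from 260 ± 29.5 to 55.9 ± 7.71 TPM, with PSPH (-1.79) and PHGDH (-1.51) of the same pathway. Amino acid transporters fell in 9 of 12 (adjusted p = 0.045; adjusted p = 0.43 with an estimated correlation), led by SLC1A4 (-1.49), SLC6A9 (-1.21) and SLC43A1 (-1.17). Chaperones and degradation factors of the endoplasmic reticulum fell in 20 of 26 and rose in 1 (median -0.73, adjusted p = 1.79e-05; 0.13 as the adjusted p with an estimated correlation). SDF2L1 (-1.95), CRELD2 (-1.47) and DERL3 (-1.27) led them, and HSPA5, the main chaperone of this compartment, went from 382 ± 35.7 to 210 ± 7.54 TPM. The call of the stress factors was lost without DMSO replicate 3 (adjusted p = 0.0843) and that of the transporters without DMSO replicate 2 (0.0541), ZG111 replicate 2 (0.0743) or ZG111 replicate 3 (0.0727).

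Nuclear subunits of complex I fell in 33 of 37 (median -0.50, camera adjusted p = 1.23e-07, and adjusted p = 0.119 with an estimated correlation). NDUFC2 (-1.44), NDUFB1 (-1.27) and NDUFB3 (-1.18) led them. The counts here include a shift of all genes toward lower values, and under median-ratio scaling complex I had 17 lower and 2 higher. ATP synthase subunits fell in 15 of 16 and rose in 1 (median -0.65, adjusted p = 9.6e-06; 0.13 as the adjusted p with an estimated correlation), with ATP5MC1 at -1.28. Complexes II and III fell in 9 of 13 (adjusted p = 0.045; 0.275 as the adjusted p with an estimated correlation), led by UQCR11 (-0.83), and complex IV in 9 of 12 (adjusted p = 0.00299; adjusted p = 0.13 with an estimated correlation), led by COX8A (-0.78). Mitochondrial ribosomal proteins fell in 45 of 78 and rose in 3 (median -0.33, adjusted p = 0.000381; adjusted p = 0.275 with an estimated correlation), with MRPL51 going from 136 ± 11.6 to 57 ± 1.12 TPM. Of the 13 mitochondrially encoded mRNAs, 9 fell and 2 rose (adjusted p = 0.0134; adjusted p = 0.424 with an estimated correlation). MT-ND6, the only mRNA of the light strand, went from 3548 ± 281 to 911 ± 30.8 TPM. The use of strand in counting is not given, so its reads may include RNA of the opposite strand. MT-ND2 (0.23) and MT-ND4L (0.22) were higher. The share of the 13 mRNAs in all TPM was 14.6% ± 1.43 in DMSO and 11.2% ± 0.55 in ZG111 (exact two-sided permutation p = 0.1, the smallest possible). With all mitochondrial genes counted, the difference of -3.33 percentage points turned to 1.46, as the share of the 2 mitochondrial rRNAs was 1.27% ± 0.111 in DMSO and 6.06% ± 0.219 in ZG111. MTRNR2L1, a nuclear gene nearly identical to part of the mitochondrial rRNA gene MT-RNR2, was called higher (2.65), and its reads cannot be separated from those of MT-RNR2. The call of the mitochondrial mRNAs was lost without ZG111 replicate 2 (adjusted p = 0.0564), and that of complexes II and III without DMSO replicate 3 (0.0843) or ZG111 replicate 2 (0.0833).

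The other 12 tested lists were not called. Their counts higher and lower were 4 and 3 of 20 aminoacyl-tRNA synthetases (adjusted p = 0.144), 2 and 6 of 18 mitochondrial chaperones and proteases (0.746), 2 and 6 of 16 genes of mitochondrial DNA transcription (0.917) and 0 and 9 of 17 of the tricarboxylic acid cycle (0.0569). They were 6 and 9 of 21 for glycolysis (adjusted p = 0.472), 6 and 5 of 17 for hypoxia (0.139), 3 and 9 of 25 for cholesterol synthesis (0.959) and 8 and 6 of 22 for lysosome and autophagy (0.231). Epithelial markers (8 and 6 of 16, adjusted p = 0.0569), mesenchymal markers (2 and 1 of 9, 0.0708) and fibroblast, immune and endothelial markers (1 and 3 of 9, 0.812) were also not called. In the last list the macrophage-associated CD68 rose by 1.59, and CD14 was lower by -0.61. Some of these lists passed when 1 library was left out. The p53 targets passed without DMSO replicate 2 (adjusted p = 0.0483), DMSO replicate 3 (0.0494) or ZG111 replicate 2 (0.036), and epithelial markers without DMSO replicate 1 (0.0355), DMSO replicate 2 (0.0322) or ZG111 replicate 3 (0.0384). Mesenchymal markers passed without ZG111 replicate 2 (0.036) or 3 (0.0384), the tricarboxylic acid cycle without DMSO replicate 2 (0.0245) or ZG111 replicate 1 (0.0412), and the synthetases without DMSO replicate 1 (0.0469). Median, mean and test did not share a sign for the synthetases, the mitochondrial chaperones, glycolysis, hypoxia, p53 targets, lysosome and the fibroblast, immune and endothelial list. With adjustment over the list alone, counts of called members differed by at most 5 from those over all genes.

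The median log2 fold change of all 16212 genes was -0.21, so list medians relative to all genes were -1.46 for DNA replication, -1.18 for mitosis, 1.09 for interferon response and -0.29 for complex I. Under median-ratio scaling 4054 genes were higher and 3577 lower (53.1% of calls higher, against 26.7%), and under quantile normalization 3645 and 3598 (50.3%). Both scalings set the median of all genes near 0 (0.007 and 0.008), so a near-even split follows by construction. With median-ratio scaling the lists of stress factors, transporters, complexes II and III, complex IV, mitochondrial mRNAs and mitochondrial ribosomal proteins lost their calls. The aminoacyl-tRNA synthetases gained theirs. Without scaling, 5799 of all 16212 genes were called lower, which counts within lists should be read beside. With median-ratio scaling 25 mitochondrial ribosomal proteins were lower and 12 higher of 78, and complexes II and III had 3 and 3 of 13. Amino acid synthesis had 10 lower and 2 higher of 15. DNA replication kept 39 lower of 39, and interferon response had 27 higher and 1 lower of 29.

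**Figure D2:**
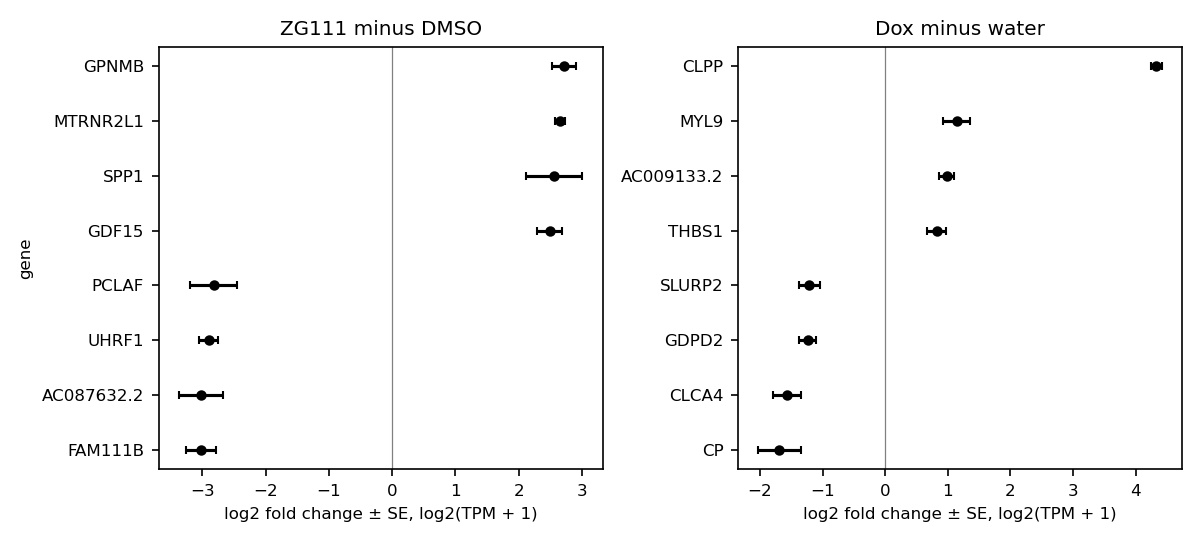
Log2 fold change (SE bars) of the 4 largest called rises and falls named in each comparison. The largest values were 2.72 for GPNMB with ZG111 and 4.33 for CLPP with Dox.

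The second comparison asked what Dox changed against water. Beside CLPP, 4 of 15 genes of serine, one-carbon, proline and asparagine synthesis fell (camera adjusted p of the list = 3.52e-05; adjusted p = 0.412 with an estimated correlation). PSAT1 fell from 95.1 ± 2.45 to 42.7 ± 0.951 TPM and ASNS, asparagine synthetase, from 59.8 ± 2.63 to 32.3 ± 0.433 TPM (SD, n = 3). DDX60L, a helicase related to an interferon-induced gene, rose from 32.7 ± 0.872 to 57.3 ± 1.12 TPM. In all, 51 genes were called higher and 77 lower, of which 5 and 11 changed at least 2-fold.

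The largest rises after CLPP were MYL9, a myosin light chain (1.14, adjusted p = 0.0402), AC009133.2 (0.98), an antisense transcript of MAZ whose reads cannot be told from MAZ without strand, the matrix protein THBS1 (0.82), SEMA7A (0.79) and DDX60L (0.79). MYL9, THBS1, DDX60L and CP each overlap a gene on the opposite strand. The largest falls were CP, the copper carrier ceruloplasmin (-1.69, adjusted p = 0.0487), CLCA4 (-1.57), GDPD2 (-1.24), SLURP2 (-1.21), which overlaps LYNX1-SLURP2, FRY (-1.15) and PSAT1 (-1.14). PLK2 and GADD45A, both p53 targets, rose by 0.72 and 0.72, while their list was not called (2 higher, 1 lower of 23).

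Of 15 genes of serine, one-carbon, proline and asparagine synthesis, 4 fell and none rose (median -0.26, camera adjusted p = 3.52e-05; adjusted p = 0.412 with an estimated correlation). They included PSAT1, ASNS (-0.87) and GPT2 (-0.75), and 5 were lower when adjusted over the list alone. Amino acid transporters (2 of 12 lower, SLC6A9 at -0.48 and SLC1A5 at -0.37; adjusted p = 4.71e-05; adjusted p = 0.386 with an estimated correlation) and integrated stress response factors (2 of 15 lower, CHAC1 and NUPR1, both -0.86; adjusted p = 0.000667; 0.615 as the adjusted p with an estimated correlation) were called in the same direction. Mitochondrial mRNAs were called lower (adjusted p = 0.00218; adjusted p = 0.615 with an estimated correlation; 0.356 under quantile normalization), with MT-CO1 alone passing at -0.37, a call lost in 10 of 22 alternatives. Their share of TPM was 16.1% ± 0.0486 in water and 15.3% ± 0.173 in Dox (exact two-sided permutation p = 0.1, the smallest possible).

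Interferon response genes were called higher as a list (median 0.32, adjusted p = 2.25e-07; adjusted p = 0.245 with an estimated correlation), with 0 of 29 called singly over all genes and 13 when adjusted over the list alone. ISG15 stood at 218 ± 7.5 TPM in water and 325 ± 6.64 TPM in Dox. NF-kB targets (1 of 19 higher, TNFAIP3 at 0.53; 7 adjusted over the list alone; adjusted p = 5.97e-05; 0.126 as the adjusted p with an estimated correlation) and mesenchymal markers (0 of 9; 5 adjusted over the list alone; adjusted p = 0.000285; adjusted p = 0.126 with an estimated correlation) were also called higher. VIM, vimentin, stood at 7.28 ± 0.885 TPM in water and 19.3 ± 6.7 TPM in Dox. Lists called higher with 0 members called over all genes were mitochondrial ribosomal proteins (median 0.07, adjusted p = 0.000481; adjusted p = 0.412 with an estimated correlation) and cholesterol synthesis (0.18, adjusted p = 0.00218; adjusted p = 0.615 with an estimated correlation; 5 adjusted over the list alone). The same held for mitochondrial chaperones (0.10, adjusted p = 0.0148; adjusted p = 0.403 with an estimated correlation), DNA replication (0.10, adjusted p = 0.0434; adjusted p = 0.84 with an estimated correlation) and mitosis (0.12, adjusted p = 0.0445; 0.84 as the adjusted p with an estimated correlation). The other 18 lists were not called, with adjusted p from 0.0536 for glycolysis to 0.907 for complex I, and for lysosome and autophagy median, mean and test did not share a sign. Without DMSO replicate 1, 2 or 3 the synthetases (adjusted p = 0.046, 0.0426 and 0.0148), the endoplasmic reticulum chaperones (0.0435, 0.0399 and 0.0364) and glycolysis (0.0433, 0.0282 and 0.0364) passed. Glycolysis also passed without ZG111 replicate 2 (0.0499) or 3 (0.0463).

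These counts depended on the fit. With only the 6 Dox and water libraries, 801 genes were higher and 614 lower. With only the 6 ZG111 and DMSO libraries, 1500 were higher and 4415 lower. The fit of all 4 groups uses 1 spread per gene. The SD of log2 differences between replicates was 0.463 to 0.497 in DMSO and 0.391 to 0.455 in ZG111. It was 0.388 to 0.4 in water and 0.386 to 0.411 in Dox. The numbers of calls are thus no measure of the relative size of the 2 effects. The Dox total of 128 became 21, 21 and 27 without water replicate 1, 2 and 3, and 28, 22 and 24 without Dox replicate 1, 2 and 3. It became 175, 227 and 201 without DMSO replicate 1, 2 and 3, and 279 without ZG111 replicate 1. Under median-ratio scaling 28.1% of calls were higher, against 39.8%. CLPP, DDX60L, GDPD2, PSAT1, ASNS, NUPR1 and PLK2 kept their call in all 23 alternatives run, while CP lost it in 14, CHAC1 in 13, SEMA7A in 12, MYL9, SLC6A9 and TNFAIP3 in 11, SLC1A5 in 10, THBS1 in 9, GPT2 in 7 and GADD45A in 6, with adjusted p up to 0.189. CLCA4 lost its call in 4 of 22 alternatives (limma adjusted p up to 0.0634), FRY in 4 of 23 (0.0666) and AC009133.2 in 1 of 23 (0.0613). Under median-ratio scaling 0 of 12 transporters were called. The call of DNA replication was lost without water replicate 1 (adjusted p = 0.055) or 2 (0.0623) or Dox replicate 2 (0.108) or 3 (0.0642). That of mitosis was lost without ZG111 replicate 1 (0.0648), water replicate 1 (0.0504), 2 (0.0545) or 3 (0.0932), or Dox replicate 1 (0.0605) or 3 (0.1), and that of mitochondrial chaperones without water replicate 2 (0.0545). No Dox-treated library of cells without an introduced gene was analysed here, so an effect of doxycycline itself is not separated.

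The third comparison asked what both treatments shared and where they differed. In both, 29 genes were called higher and 49 lower, where independent lists would share 6.7 and 27.5, while 10 were higher with ZG111 and lower with Dox (10 by the same reckoning) and 5 the reverse (18.2). The 78 shared calls became 9 to 12 without any 1 of the Dox or water libraries, 120 without DMSO replicate 2 and 151 without ZG111 replicate 1. The genes higher in both included SEMA7A (1.38 with ZG111, 0.79 with Dox), DDX60L (0.91 and 0.79), MIR17HG (1.41 and 0.74), the host of a microRNA cluster, and CIART (0.70 and 0.69). The genes lower in both included CP (-1.36 and -1.69), PSAT1 (-2.20 and -1.14), the carbonic anhydrase CA12 (-1.18 and -1.06) and SLURP2 (-0.97 and -1.21). The Dox call of MIR17HG was lost in 14 of 23 alternatives, that of CA12 in 12 of 22, that of CIART in 7 of 23 and that of SLURP2 in 4 of 23. Across the 16212 genes, which are not independent replicates, the 2 sets of fold changes correlated with Pearson r = 0.164 and Spearman rho = 0.209. No control library was shared between the 2 sets.

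The effects themselves differed for 4768 genes, 3610 with a larger value with Dox and 1158 with a larger value with ZG111. Under median-ratio scaling the split was 2011 and 2422 (45.4% higher against 75.7%) and under quantile normalization 2067 and 2216 (48.3%). The median difference over all genes was 0.22 without scaling. Both scalings set it near 0 by construction (0 and -0.009), so the near-even splits do not test the excess in 1 direction. UHRF1 (difference 3.15, adjusted p = 7.72e-06) and FAM111B (3.19) fell with ZG111 and stood at 24.1 ± 0.523 and 13.1 ± 0.692 TPM in Dox against 20 ± 1.34 and 11.6 ± 0.37 TPM in water. GDF15 (-2.79, adjusted p = 5.94e-05), GPNMB (-3.17) and SPP1 (-3.13) rose with ZG111 and were not called with Dox. Of the 30 lists, 17 differed with the preset correlation and 0 with an estimated one (lowest adjusted p = 0.0936). ASNS was called lower in both, with a difference of -0.01 (SE 0.11, adjusted p = 0.953).

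The vehicle groups also differed, which bears on every comparison of the 2 effects. Between water and DMSO, 2007 genes were higher in water and 1569 lower, of which 433 and 115 differed at least 2-fold. IFI6, an interferon-induced gene, stood at 16.9 ± 6.95 TPM in DMSO and 274 ± 1.45 TPM in water (log2 difference 4.01, limma adjusted p = 6.89e-07), and SPRR2E (3.54) and FGFBP1 (3.36) were also higher in water. SYBU (-2.57), RPPH1 (-2.65) and RNVU1-18 (-2.52) were lower in water, although the DMSO spread was wide for RPPH1 (35.1 ± 47.1 TPM) and RNVU1-18 (64.9 ± 78.9 TPM), whose calls were lost in 10 and 11 of 23 alternatives. The count was 2325 without water replicate 2 and 2351 without water replicate 3. Vehicle, cells and day of culture cannot be told apart, since the labels give no batch and each vehicle group has 1 treatment.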

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

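Results are given here whose effect differed between the 2 treatments by the test of the difference itself, as Dox effect minus ZG111 effect on the log2 scale; the tests of carry-through, nuclear copies, mitochondrial RNA as a whole, scaling and the splits for the correlation were chosen only after the results they bear on were seen. CLPP differed by 4.28, CLPX by 0.43, AC020909.3, an antisense transcript of EMC10, by 3.42, FAM111B by 3.19, UHRF1 by 3.15 and AC087632.2 by 3.06. The value of AC020909.3 ran from 1.41 to 6.83 over 21 alternatives, and its reads cannot be told from EMC10 without strand. The difference was -4.87 for RNVU1-7, a small nuclear RNA with near-identical copies whose call was lost in 11 of 22 alternatives, -3.32 for MTRNR2L1, -3.17 for GPNMB, -3.13 for SPP1 and -2.79 for GDF15. The CLPX difference was 0.17 under median-ratio scaling (limma adjusted p = 0.228).

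Among the lists, the median difference was 1.69 for DNA replication, 1.44 for mitosis, 0.70 for endoplasmic reticulum chaperones, 0.66 for serine, one-carbon, proline and asparagine synthesis, 0.61 for ATP synthase, 0.54 for complex I, 0.39 for mitochondrial ribosomal proteins, 0.38 for complex IV, 0.31 for mitochondrial mRNAs, 0.29 for complexes II and III and 0.23 for the tricarboxylic acid cycle. It was -0.70 for interferon response, -0.31 for NRF2 targets, -0.30 for integrated stress response factors and -0.12 for immediate early genes. For the BCL2 family and death receptors it was -0.10, and for aminoacyl-tRNA synthetases -0.07. Under median-ratio scaling 4 of these calls were lost: complex IV (0.12, adjusted p = 0.157), mitochondrial mRNAs (0.04, 0.52), complexes II and III (0.03, 0.512) and the tricarboxylic acid cycle (-0.03, 0.52). Under that scaling the median for mitochondrial ribosomal proteins was 0.13. It was -0.36 for immediate early genes, -0.33 for the BCL2 family and death receptors, and -0.33 for the synthetases. With an estimated correlation, adjusted p ranged from 0.0936 to 0.961 over the 30 lists. With the preset correlation, complexes II and III lost the call without DMSO replicate 3 (adjusted p = 0.0756) or ZG111 replicate 2 (0.0788), mitochondrial mRNAs without the same libraries (0.0756 and 0.154) and the synthetases without DMSO replicate 3 (0.0508). The tricarboxylic acid cycle lost it without DMSO replicate 1 (0.0704) or 3 (0.0546), water replicate 3 (0.0526) or Dox replicate 1 (0.0642). Lists gained a call too: hypoxia without DMSO replicate 2 (0.036) or ZG111 replicate 3 (0.0284), NF-kB targets without DMSO replicate 1 (0.0254), cholesterol synthesis without DMSO replicate 2 (0.0183), and fatty acid synthesis without DMSO replicate 3 (0.0255), ZG111 replicate 3 (0.0407) or water replicate 1 (0.0475). Median, mean and test did not share a sign for glycolysis, hypoxia, p53 targets, lysosome, epithelial, mesenchymal and fibroblast lists.

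The 2 mitochondrial rRNAs, which were chosen after their values were seen, rose with ZG111 (MT-RNR2 by 2.33 and MT-RNR1 by 2.01) and fell with Dox (-0.62 and -0.36), while MT-ND6 fell with ZG111. Both rRNAs were also lower in water than in DMSO (-0.91, limma adjusted p = 4.62e-06, and -1.29, limma adjusted p = 7.82e-07). These vehicle differences were larger than the falls with Dox. Carry-through of RNA without a poly(A) tail would raise other such RNAs. The median of 112 genes of these classes was -0.22 (95% interval over genes -0.41 to 0), with 5 called higher and 7 lower. Many of these genes are related copies with scattered values, such as RNU1-1 (3.03) and RNU1-2 (-2.7), and genes are not replicates. These classes thus showed no general rise, but they cannot settle whether rRNA was carried through. Reads shared with nuclear copies stay open: MTRNR2L1, the only tested copy, gained 0.926% of what MT-RNR2 gained, but the reads of near-identical copies cannot be assigned. More mitochondrial RNA of every kind would raise the mRNAs, whose median was -0.35. No biological explanation was tested.

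Most genes called with ZG111 were lower (2114 higher, 5799 lower). The counts were 4054 and 3577 under median-ratio scaling and 3645 and 3598 under quantile normalization. Both scalings set the median change of all genes near 0 (0.007 and 0.008). A near-even split thus follows by construction and cannot tell whether the excess of lower calls is an artifact. A few genes taking most of the TPM may account for part of that excess. The 20 genes with the largest gain took 7.36% more of the TPM. Without them the median of all genes moved from -0.21 to -0.12 (-0.17 to -0.05 with 1 library of each group left out). That range reaches past -0.1, the bound set beforehand, so this explanation stays open. Leaving out genes picked for their gain raises the rest by arithmetic, so the direction of the move is no evidence. GC content or gene length would leave some class of genes unshifted, but the medians of 9 classes ran from -0.26 to -0.19. A shift common to all genes puts every class below 0, so the bound alone cannot exclude a bias beside it. Across genes the Spearman rho of fold change was 0.00118 with GC content and 0.0167 with length. The shift thus did not vary steadily with either. TPM holds no absolute amounts, so a fall in RNA per cell was not tested.

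The list of amino acid synthesis genes was called lower in both comparisons, with 13 of 15 members lower with ZG111 and 4 of 15 with Dox (adjusted p = 0.275 and 0.412 with an estimated correlation). Scaling between libraries is argued against, since the list median nearest 0 over both comparisons and both scalings was -0.24. Under median-ratio scaling 10 of the 15 members were lower with ZG111 and 2 were higher. With the preset correlation the list kept its call in both comparisons, whichever 1 of the 12 libraries was left out (highest camera adjusted p = 0.000877). That p-value treats the genes as nearly independent, while their estimated correlation was 0.409. The same test called up to 14 lists on other splits of the ZG111 and DMSO libraries. Leaving out libraries under this test thus cannot decide whether a single library gave the pattern. The same list was called lower in water than in DMSO (median -0.94, adjusted p = 5.66e-09; adjusted p = 0.131 with an estimated correlation). No biological explanation was tested, nor were the medium and density of the cultures.

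Other splits of the libraries were counted for each result. For 3 against 3 there are 10 splits, too few for a share under 0.05, and in each case only the real split, 1 of 10, reached the real value. The real counts against the highest of the other splits were 2114 and 5799 against 1 for ZG111, 51 and 77 against 1 for Dox, and 3576 against 0 for the vehicles. They were 18 against 14 lists for ZG111 and 12 against 1 for Dox. Over 100 splits of both pairs of groups, 2 reached the number of genes that differed (4768 against 4816). As other splits of the ZG111 and DMSO libraries call at most 1 gene per direction, a count of this size can follow from the ZG111 effect alone and does not test the difference. For the correlation, 3 of 100 splits reached the real value with the filter used (0.164, against 0.17 for the highest other split). With a mean of at least 5 TPM, 5 splits did (0.155). As this test was also chosen after the values were seen, chance was not excluded for the correlation. For genes called in both the real split alone reached the count (1 split, 78 against 1), but other splits call at most 1 gene per direction in an arm, so this count does not test the overlap. Chance was not excluded for the lists that differed (10 splits, 17 against 19).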

How the results depend on the processing

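All alternatives were planned before the data were examined, and the cause of a change was not tested unless given. CLPP in Dox against water kept its direction and call under all (4.21 to 4.38). In ZG111 against DMSO its fold change ran from -0.07 to 0.31. Requiring 2-fold as well left 254 and 1234 genes for ZG111, 5 and 11 for Dox, 1338 for the difference, 548 for the vehicles and 4 in both; adjusted p under 0.01 left 7 and 16 for Dox, 2503, 1713 and 10, by construction. With an estimated correlation 0 lists were called in each of the 3 comparisons. For ZG111, median-ratio scaling gave 4054 higher and 3577 lower and quantile normalization 3645 and 3598, near-even splits that follow from both scalings by construction. For Dox, the higher count was 91 with pseudocount 5, 23 with no filter, 25 with median-ratio scaling, 801 with only its own libraries, 20 without a variance trend and 701 with library weights. The lower count was 37 with no filter, 152 with quantile normalization, 614 with only its own libraries, 38 without a trend and 598 with weights. Genes called in both numbered 26, 47, 124, 29 and 555 with no filter, median-ratio scaling, quantile normalization, no trend and weights. The correlation was 0.155 with a mean of at least 5 TPM, reached by 5 of 100 splits. CLPX with ZG111 was 0.04 under median-ratio scaling, against -0.22. Counting all mitochondrial genes, with their rRNA, turned the share change for ZG111 from -3.33 to 1.46 percentage points and made it -1.03 for Dox.

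Without each library in turn, counts ranged from 1788 to 2090 higher and 4872 to 5816 lower for ZG111, 7 to 1.2e+02 (rounded) higher and 13 to 161 lower for Dox, 3807 to 4856 for the difference, 2325 to 4293 for the vehicles and 9 to 151 in both. Lists ranged from 17 to 20, 9 to 15 and 14 to 19, and the correlation from 0.13 to 0.179. CLPP in Dox against water ranged from 4.3 to 4.38, and the change in mitochondrial share from -4.06 to -2.63 and -0.924 to -0.764. The replicate block gave 29 higher and 22 lower for Dox and 30 in both. Deviations from the group mean correlated between same-numbered libraries at 0.108, 0.036 and 0.055 (ZG111 and DMSO) and 0.09, 0.016 and 0.056 (Dox and water). Between differently numbered libraries the values ran from -0.085 to 0.041. Replicate 2 of ZG111 and of Dox correlated slightly better with replicate 3 of its vehicle (0.041 and 0.033). All these values are small, so whether the numbers pair the libraries stays open. Read depth, unknown from TPM, limits low genes.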

Other observations

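The lists were also compared between the vehicle groups, a test chosen after the data were seen, as were the genes named here. Integrated stress response factors were lower in water than in DMSO in 12 of 15, with none higher (median -1.15, camera adjusted p = 6.62e-11; adjusted p = 0.12 with an estimated correlation). DDIT3 stood at 164 ± 61 TPM in DMSO and 28.9 ± 2.26 TPM in water, and TRIB3 at 279 ± 126 and 43.9 ± 0.589 TPM (SD, n = 3). NF-kB targets were higher in water in 12 of 19 (median 0.72, adjusted p = 8.34e-09), the only list of 30 called with an estimated correlation (adjusted p = 0.0455). Interferon genes (21 of 29 higher, 1 lower, median 0.84, camera adjusted p = 3.53e-13) and cholesterol synthesis (17 of 25 higher) were called higher in water. Their adjusted p was 0.0582 and 0.131 with an estimated correlation. The interferon median was near that with ZG111 (0.88) and above that with Dox (0.32). Mesenchymal markers (6 of 9 higher, median 0.89, adjusted p = 2.97e-05; adjusted p = 0.0582 with an estimated correlation) and fibroblast, immune and endothelial markers (7 of 9 higher, median 0.81, adjusted p = 0.00138; adjusted p = 0.0582 with an estimated correlation) were also called higher in water. Among them, FN1 differed by 1.74, LUM by 1.72 and CDH5 by 1.19 on the log2 scale. FOS stood at 39.8 ± 3.92 TPM in DMSO and 389 ± 7.3 TPM in water.

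SQSTM1, a receptor of selective autophagy, rose with ZG111 from 418 ± 37.1 to 1244 ± 140 TPM, while the list of lysosome and autophagy genes was not called. HSPD1, a mitochondrial chaperonin, rose with ZG111 by 0.45, and LONP1, another matrix protease, stood at 62.6 ± 17.9 and 61.5 ± 3.39 TPM. Of 17 fibroblast, immune, endothelial, acinar, endocrine and hepatocyte markers that did not pass the filter, DCN reached the highest TPM in any library, 3.43.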
